A study of Mus musculus with 12 samples.

How the data were processed

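The series measured liver RNA of 12 mouse samples on Affymetrix arrays, 9 on the 430A design and 3 on the 430 2.0 design. Per the labels' protocols, mice were 10 weeks of age, were kept on NTBC or given water for 14 days, RNA was isolated with RNeasy from 10 mg of liver stabilized in RNAlater, and a one-cycle procedure made the biotinylated cRNA. The values are the intensity signals the authors deposited, 1 per probe set and array, on a linear scale, made with GCOS 1.4.0.036 and MAS5 per the submitters' processing notes. The mean between the 2nd and 98th percentile of signal was checked and lay near 350 on each array, so the authors had scaled the arrays to a common level. Scan dates, mouse strain and sex are not given in the sources used here. The normal group follows the titles and pools 4 conditions with 1 mouse each.

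The values were taken to log2(signal + offset), with the offset at the 10th percentile of all signals of a table (9.9 on 430A, 3.8 on 430 2.0), so fold changes, which are on this scale, are understated for dim probe sets. Of 22690 probe sets on 430A and 45101 on 430 2.0, 64 on each are controls and were left out. Probe sets at or above their array's 40th percentile on at least 2 arrays were tested, 15307 on 430A and 26925 on 430 2.0. All 9 arrays of 430A entered 1 limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes with the intensity trend), so that the groups shared 1 estimate of the spread, with 6 residual and 5.01 prior degrees of freedom. The 430 2.0 fit had 1 residual degree of freedom. Adjusted p-values are Benjamini-Hochberg values from limma over all probe sets tested, and a probe set passed at an adjusted p under 0.05. The tables of both designs were scaled separately, so tests were made within a table only. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

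Gene symbols came from GEO's platform annotation and were set against the gene table of the mouse assembly GRCm38.p6 by Entrez identifier, with 20351 probe sets of 430A and 34741 of 430 2.0 matched; the table was used for names only. On 430A 20380 probe sets had 1 symbol, 691 several and 1555 none, covering 12393 genes; on 430 2.0 these were 34945, 932, 9160 and 18193. No gene was named from a probe set with several symbols. A gene's representative was its probe set of highest mean log2 signal over all arrays of the table. Named for each comparison were the 10 largest rises and 10 largest falls among representatives that passed and whose groups did not overlap, without clone or model names. Added were Fah and Cdkn1a, and from each gene list described up to 4 members that passed with the largest changes, or the 2 with the smallest p where fewer than 2 passed. On 430 2.0 the same genes were read. The probe set without a symbol in the double knockout against single knockout comparison, Cdkn2b and other list members follow from these rules, and growth hormone genes were named for a test in the closing part.

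Fixed gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, on representative probe sets, for lists with at least 5 tested members. The 34 lists covered p53 targets, G1/S and DNA replication, G2/M and mitosis, cell cycle inhibitors, DNA repair, Nrf2 and glutathione targets, ATF4 and the unfolded protein response, heat shock proteins, apoptosis regulators, phenylalanine and tyrosine catabolism, urea cycle, gluconeogenesis and amino acid catabolism, glycolysis, bile acids, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, xenobiotic metabolism, acute phase, complement and coagulation, hepatocyte identity, fetal liver, circadian clock output, sex-linked transcripts, male- and female-biased liver genes, and markers of cholangiocytes, macrophages, lymphocytes, neutrophils, erythroid cells, stellate cells, endothelial cells, and adipose tissue, pancreas and kidney. List p-values were adjusted over the lists of a comparison, and members were also adjusted over the list alone. Groups, comparisons, lists, naming rule and most alternatives were chosen before the data were examined.

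The fits were tested on simulated data of 15307 probe sets, drawn independently of each other, with 100 changed 2-fold and 100 changed 4-fold. Recovery was 78% and 98% for Fah off against normal, 49% and 97% for Fah p21 off against normal, and 42% and 94% for Fah p21 off against Fah off, with 13, 14 and 8 false calls. For the last comparison camera called 10 of 10 raised lists and 0 of 10 unchanged ones. The genes of these simulated lists were uncorrelated, so false calls among correlated genes, as in the real lists, were not tested. No pair of the 36 pairs of 430A arrays shared more than 0.407% identical signals, so none was treated as a duplicate. The alternatives were no filter or a filter at the 60th percentile, no offset or the 25th percentile, quantile normalization, scaling to a common median, limma without the trend or robust, a 2-fold minimum, representative probe sets only, fits of 2 groups, the replicate number as a block, other choices of control mice, other probe sets of a gene, the mean over a gene's probe sets, and leaving out each array in turn. Controls of wildtype mice only, median scaling for gene lists, and the other controls and fits for the named genes between the knockouts were added after seeing the data.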

Results

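Liver RNA of adult mice, 10 weeks of age, was measured on Affymetrix expression arrays. Fah encodes fumarylacetoacetate hydrolase, the last enzyme of tyrosine breakdown, and NTBC is a drug that blocks an earlier step, so that Fah knockout mice on it do not accumulate the toxic late products. p21 is the product of Cdkn1a, an inhibitor of cyclin-dependent kinases and a target of p53. On the 430A array the normal group held 4 livers, 1 each of a wildtype mouse on water, a wildtype mouse on NTBC, a Fah knockout on NTBC and a Fah p21 double knockout on NTBC. The Fah off group held 3 Fah knockout livers after 14 days without NTBC, and the Fah p21 off group held 2 double knockout livers after the same time. The 430 2.0 array held 2 further double knockout livers off NTBC and 1 normal liver. That liver was taken to be of the same mouse as normal 4 on 430A, since both titles give the same replicate number. The titles call the arrays biological replicates. The number of arrays limits the precision of each value. Changes are log2 fold changes ± SE of the log2(signal + offset) values. The p-values set them against the spread within the groups, which limma moderates by that of other probe sets. In the normal group that spread includes differences between its 4 conditions.

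The targeted genes were read first. Fah signal was 6868 and 7120 in the wildtype livers, 181.9 and 233 in the knockout livers on NTBC, and between 100.8 and 114.2 in all 5 livers off NTBC on 430A. The array holds 2 probe sets for Cdkn1a, called here the _a_at and the _at probe set after the ends of their identifiers, and they differed from each other in the double knockout. The _a_at probe set was at 14.7 to 51.4 in the normal livers and at 989.5 to 1862 in the Fah off livers, but at 9.5 and 8.2 in the double knockout livers off NTBC. The _at probe set was at 75.2 to 257.7, 2814 to 3936, and 1828 and 2060 in the same groups. A probe set outside the deleted part of a gene checks no label, and the place of these probe sets relative to the deletion is not given in the sources used here. The 430 2.0 livers had the same split, with the _a_at probe set at 4.4 and 5.5 and the _at probe set at 3789 and 3655 off NTBC, against 12.7 and 389.1 in the normal liver.

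**Figure D1:**
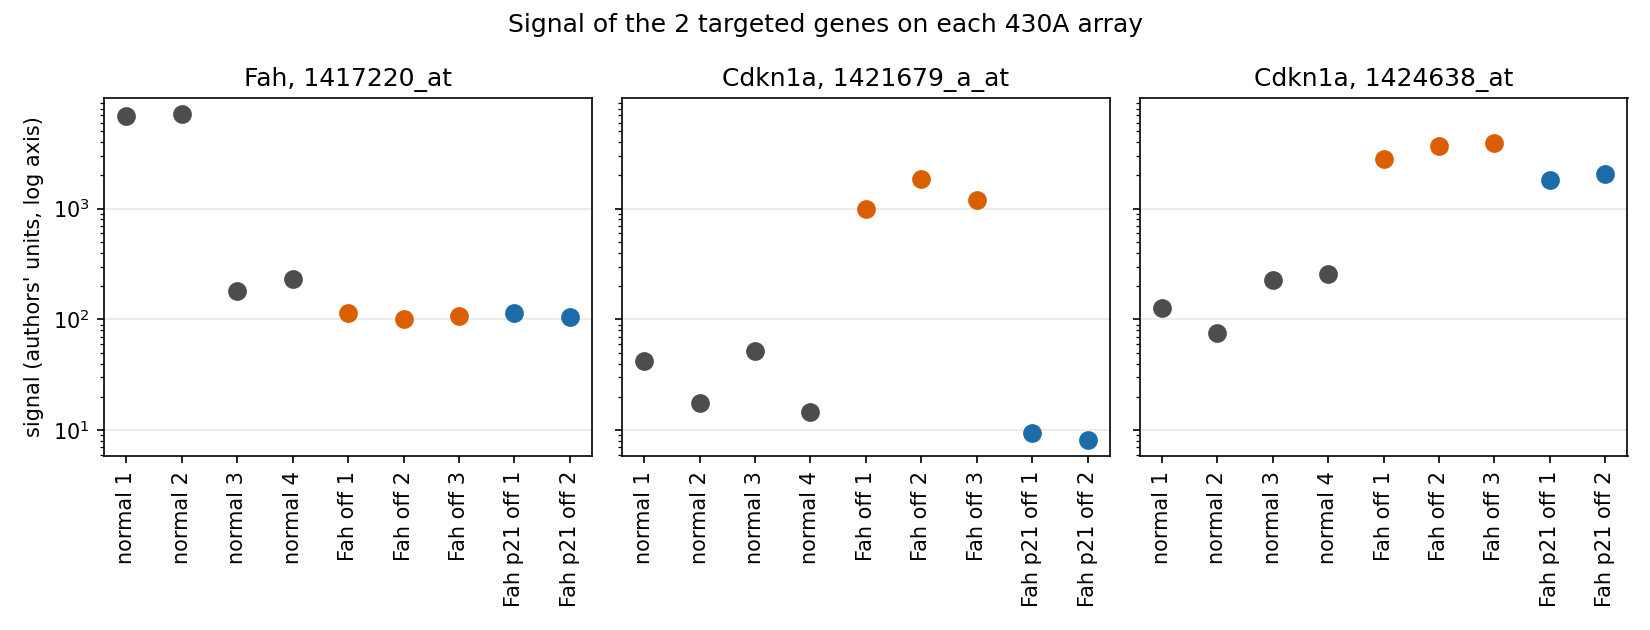
Signal in the authors' units (vertical log axis) of the Fah probe set and both Cdkn1a probe sets on each 430A array (horizontal axis), 1 point per array, coloured by group. Fah separates the wildtype livers (6868 and 7120) from every knockout liver. The Cdkn1a _a_at probe set is at 9.5 and 8.2 in the double knockout livers off NTBC.

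The first comparison asked what 14 days without NTBC did to Fah knockout liver (n = 3) against the normal livers (n = 4). Most Nrf2 targets (23 of 26), p53 targets (17 of 25) and fetal liver genes (11 of 17) rose, and most genes of complement and coagulation (23 of 25), bile acid synthesis and transport (13 of 17) and hepatocyte identity (14 of 18) fell. Afp, the main serum protein of fetal liver, rose 79.3-fold (6.31 ± 0.26), the surface protein gene Ly6d rose 167-fold (7.38 ± 0.20), and the carbonyl reductase gene Cbr3 rose 92.7-fold (6.53 ± 0.42). Hsd3b5, a steroid dehydrogenase gene of male mouse liver, fell (-8.34 ± 0.19), and so did the organic anion transporter gene Slco1a1 (-7.43 ± 0.20). The serine synthesis gene Psat1 (6.19 ± 0.19), the TWEAK receptor gene Tnfrsf12a (5.51 ± 0.33), Gpx2 (5.37 ± 0.21), Pdk4 (5.12 ± 0.19), Serpina5 (5.06 ± 0.50), Spink1 (4.72 ± 0.19) and Sult2a2 (5.56 ± 0.29) completed the 10 largest rises. The largest falls also held the complement subunit genes C8b (-6.74 ± 0.40) and C8a (-5.20 ± 0.33), Cyp2c50 (-5.90 ± 0.56), Cyp2c54 (-5.82 ± 0.18), Cyp4f14 (-4.99 ± 0.21), Saa1 (-5.19 ± 0.49), Upp2 (-4.90 ± 0.35) and Mug1 (-4.53 ± 0.24). Sult2a2 and the Cyp2c genes belong to families of near-identical copies, so their signal is uncertain between members. Among the normal livers Cyp2c54 was highest in normal 2 (5624 against 3718 to 3857) and Upp2 in normal 3 (3405 against 1789 to 1966). Among these genes the highest adjusted p was 2.12e-05. Of 15307 probe sets tested with limma, 5437 passed, 3082 higher and 2355 lower off NTBC (2934 and 2736 after quantile normalization, and 2635 and 2726, with more lower than higher, with median scaling), and 2265 of them changed at least 2-fold (1348 higher, 917 lower). By 1 representative probe set per gene, 3327 of 9195 tested genes passed, 1814 higher and 1513 lower. With only the genotype-matched mouse on NTBC as control the count was 2572.

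Of the Nrf2 targets, genes of glutathione synthesis and oxidant defence, 23 of 26 rose and 3 did not pass (24 rose adjusted over the list alone), with median 1.44, camera adjusted p = 7.16e-13, and adjusted p = 0.108 with an estimated correlation. The cystine importer gene Slc7a11 (3.97 ± 0.31), Mgst3 (3.54 ± 0.22) and the heme oxygenase gene Hmox1 (3.47 ± 0.41) had the largest rises after Cbr3. Among p53 targets 17 of 25 rose and 8 did not pass (17 rose adjusted over the list alone), with median 1.15, camera adjusted p = 3.75e-08, and adjusted p = 0.102 with an estimated correlation. These included Cdkn1a by both probe sets (5.10 ± 0.35 for _a_at and 4.39 ± 0.33 for _at), the growth arrest gene Gadd45a (3.37 ± 0.49), Plk2 (3.25 ± 0.21) and Gtse1 (3.11 ± 0.29), the last a gene that works in the mitotic spindle. Of the fetal liver list 11 of 17 rose and 6 did not pass (13 rose adjusted over the list alone), with median 1.85, camera adjusted p = 2.4e-07, and adjusted p = 0.102 with an estimated correlation, and beside Afp and Ly6d the glypican gene Gpc3 rose (3.70 ± 0.33). Of the cholangiocyte markers 6 of 8 rose and 2 did not pass (6 rose adjusted over the list alone), with median 2.15, camera adjusted p = 0.000947, and adjusted p = 0.108 with an estimated correlation. Krt23 (3.07 ± 0.46), Prom1 (2.86 ± 0.33), Bicc1 (2.73 ± 0.21) and Cldn4 (2.21 ± 0.30) were among those that rose. With no filter on dim probe sets the median of that marker list was 0.74. Of the heat shock genes 8 of 13 rose and 5 did not pass (8 rose adjusted over the list alone), with median 0.73, camera adjusted p = 0.00307, and adjusted p = 0.402 with an estimated correlation, and the small heat shock protein gene Hspb1 rose most (3.59 ± 0.23). The named genes had adjusted p of at most 0.000425.

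Among hepatocyte functions, complement and coagulation had the lowest camera p of the lists. In it 23 of 25 fell and 2 did not pass (23 fell adjusted over the list alone), with median -1.87, camera adjusted p = 4.33e-16, and adjusted p = 0.102 with an estimated correlation. The clotting factor gene F7 fell beside C8a and C8b (-2.95 ± 0.19). Of the genes of gluconeogenesis and amino acid catabolism 1 of 18 rose, 15 fell and 2 did not pass (1 rose and 16 fell adjusted over the list alone), with median -1.33, camera adjusted p = 1.17e-09, and adjusted p = 0.102 with an estimated correlation. The histidine ammonia-lyase gene Hal (-3.88 ± 0.16) and the proline dehydrogenase gene Prodh (-2.92 ± 0.19) fell most. In the urea cycle 8 of 9 fell and 1 did not pass (9 fell adjusted over the list alone), with median -1.07, camera adjusted p = 1.88e-06, and adjusted p = 0.108 with an estimated correlation, including Asl (-2.36 ± 0.22) and Cps1 (-1.87 ± 0.12). In phenylalanine and tyrosine catabolism 9 of 10 fell and 1 did not pass (9 fell adjusted over the list alone), with median -1.11, camera adjusted p = 2.09e-05, and adjusted p = 0.163 with an estimated correlation. Tat, the aminotransferase that starts tyrosine breakdown, fell (-2.96 ± 0.21), as did Got1 (-2.26 ± 0.28). Fah itself is a member of that list, and its normal group mixes wildtype and knockout livers. Relative to the wildtype mean the list averaged -0.68 in normal 3, -0.89 in normal 4 and -1.76, -1.76 and -1.72 in the Fah off livers. Its 9 genes other than Fah, read after the results were seen, averaged -0.18 and -0.45 in normal 3 and 4 and -1.31, -1.29 and -1.25 in the Fah off livers. Of the bile acid genes 1 of 17 rose, 13 fell and 3 did not pass (1 rose and 13 fell adjusted over the list alone), with median -1.23, camera adjusted p = 1.23e-07, and adjusted p = 0.108 with an estimated correlation. The uptake transporter gene Slco1b2 (-2.27 ± 0.31) and the oxysterol hydroxylase gene Cyp7b1 (-2.56 ± 0.24) were among those that fell. Of the hepatocyte identity genes 14 of 18 fell and 4 did not pass (15 fell adjusted over the list alone), with median -0.53, camera adjusted p = 3.75e-08, and adjusted p = 0.102 with an estimated correlation and a median of -0.31 after quantile normalization. Its largest falls were Hrg (-1.74 ± 0.12), the transcription factor gene Cebpa (-1.07 ± 0.11) and Vtn (-1.03 ± 0.11). Among these genes the highest adjusted p was 0.000206.

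In cholesterol synthesis 13 of 19 fell and 6 did not pass (15 fell adjusted over the list alone), with median -1.42, camera adjusted p = 5.16e-06, and adjusted p = 0.404 with an estimated correlation, led by Tm7sf2 (-2.79 ± 0.23) and Nsdhl (-2.61 ± 0.20). In fatty acid synthesis 10 of 16 fell and 6 did not pass (10 fell adjusted over the list alone), with median -1.24, camera adjusted p = 0.000481, and adjusted p = 0.156 with an estimated correlation, led by Thrsp (-4.12 ± 0.58), the desaturase genes Scd1 (-3.20 ± 0.45) and Fads1 (-2.67 ± 0.22), and the synthase gene Fasn (-1.77 ± 0.26). Scd1 was at 3436 in normal 4 and at 9781 to 10327 in the other normal livers. Of the acute phase genes 4 of 27 rose, 18 fell and 5 did not pass (4 rose and 19 fell adjusted over the list alone), with median -0.73, camera adjusted p = 5.08e-05, and adjusted p = 0.317 with an estimated correlation. Saa2 (-3.03 ± 0.40) and Itih4 (-2.93 ± 0.29) fell while the metallothionein gene Mt1 rose (3.09 ± 0.42). Of the xenobiotic genes 1 of 22 rose, 10 fell and 11 did not pass (2 rose and 10 fell adjusted over the list alone), with median -0.59, camera adjusted p = 0.000393, and adjusted p = 0.108 with an estimated correlation. Cyp2j5 fell (-3.38 ± 0.32) and the aryl hydrocarbon receptor target Cyp1a1 rose (3.75 ± 0.23). Of the male-biased liver genes 8 of 9 fell and 1 did not pass (8 fell adjusted over the list alone), with median -2.56, camera adjusted p = 6.88e-07, and adjusted p = 0.102 with an estimated correlation, among them the elongase gene Elovl3 (-4.03 ± 0.51). The named genes had adjusted p of at most 0.000338. No list's camera call in any of the comparisons held with an estimated correlation.

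Of the G1/S and replication genes 5 of 26 rose, 4 fell and 17 did not pass (6 rose and 4 fell adjusted over the list alone), with median 0.28 and camera adjusted p = 0.365. Mcm2 (2.69 ± 0.21) and the cyclin gene Ccnd1 (2.06 ± 0.27) rose while the thymidine kinase gene Tk1 (-3.03 ± 0.47) fell. Of the G2/M and mitosis genes 4 of 27 rose and 23 did not pass (3 rose adjusted over the list alone), with median 0.14 and camera adjusted p = 0.344. Pttg1 (1.24 ± 0.19) and Cks2 (0.72 ± 0.15) rose. Of the cell cycle inhibitors other than Cdkn1a, 4 of 13 rose, 1 fell and 8 did not pass (4 rose and 1 fell adjusted over the list alone) with median 0.18 and camera adjusted p = 0.575. Cdkn2b (3.21 ± 0.36) and Cdkn1c (2.90 ± 0.39) rose and Rbl2 (-1.17 ± 0.14) fell. Of the macrophage markers 4 of 19 rose and 15 did not pass (4 rose adjusted over the list alone), with median 0.40, camera adjusted p = 0.0193, and adjusted p = 0.646 with an estimated correlation, Lyz2 (1.34 ± 0.19) among them. That macrophage call ended without normal 1 (median 0.36), normal 2 (0.29) or Fah off 1 (0.34), and without normal 4 the median was 0.63. Of the stellate cell and matrix markers 3 of 19 rose and 16 did not pass (3 rose adjusted over the list alone), with Lum at 1.06 ± 0.17. The list had median 0.28 and camera adjusted p = 0.107. It passed without Fah off 3 (median 0.43) and over the mean of each gene's probe sets (0.36). Among these genes the highest adjusted p was 0.0035.

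**Figure D2:**
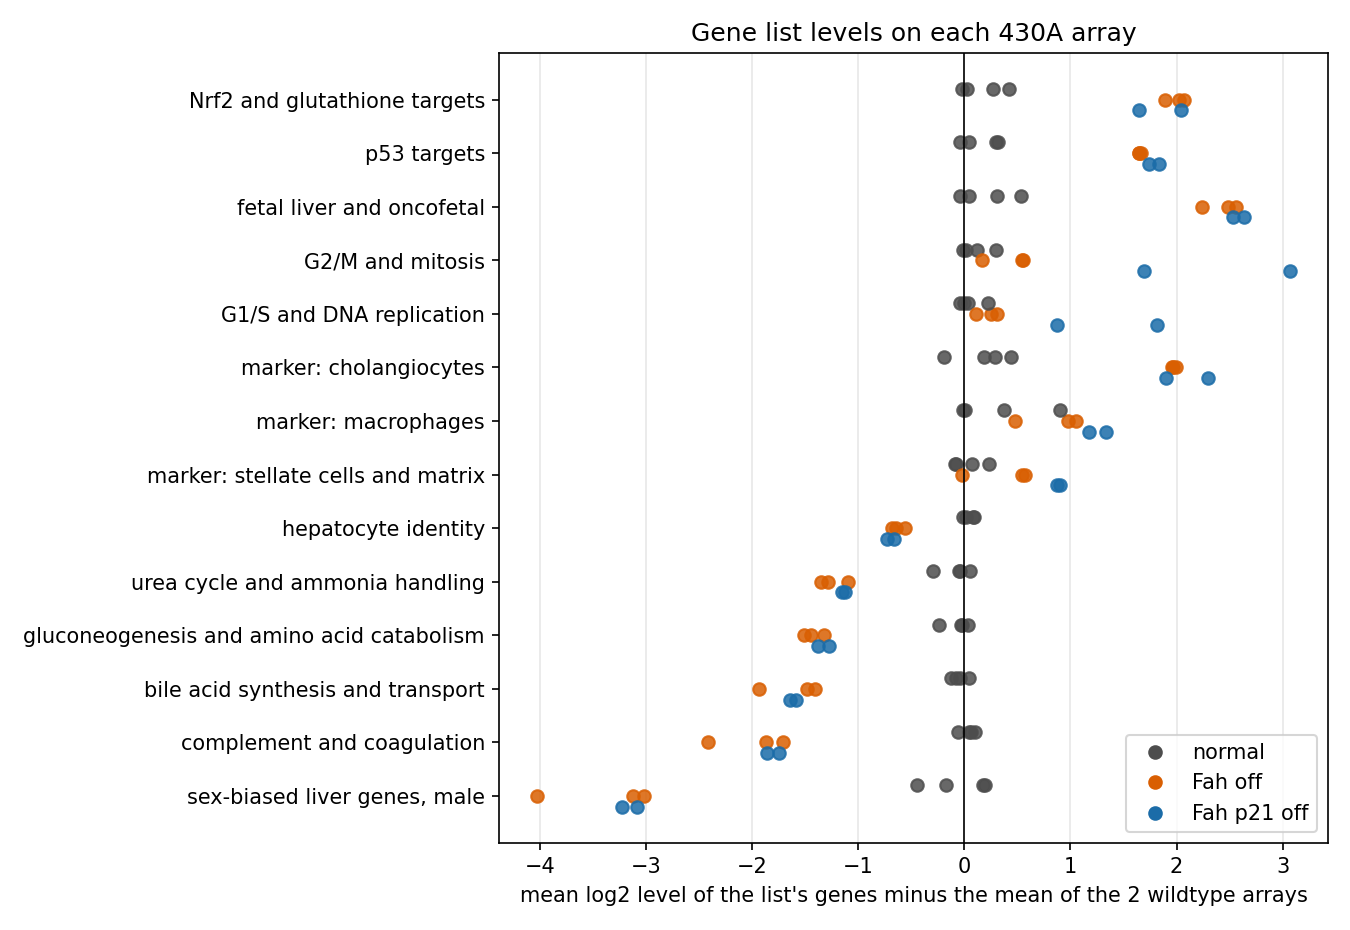
Mean log2 level of the genes of 14 lists (vertical axis) on each 430A array, minus the mean of both wildtype arrays (horizontal axis, log2). Each point is 1 array, with normal in grey, Fah off in orange and Fah p21 off in blue. The G2/M and mitosis list sits at 0.17 to 0.55 in the Fah off livers and at 1.69 and 3.07 in the Fah p21 off livers.

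The second comparison asked what the same withdrawal did to double knockout liver (n = 2) against the normal livers (n = 4). Of the G2/M and mitosis genes 24 of 27 rose, as did 19 of 26 G1/S genes, 23 of 26 Nrf2 targets and 14 of 17 fetal liver genes, while 23 of 25 genes of complement and coagulation fell. The G2/M list has 38 members, of which 27 were tested, and the G1/S list 36, of which 26 were tested. A gene could pass the filter through the 2 Fah p21 off livers alone. The shares and medians of these cell cycle lists may therefore be too high. The mitotic kinase gene Cdk1 rose 25.8-fold (4.69 ± 0.45), the replication helicase gene Mcm6 rose 30.8-fold (4.95 ± 0.75) from normal signals of 5.9 to 19.1, Ly6d rose by 7.18 ± 0.23 and Afp by 5.82 ± 0.30. Hsd3b5 (-8.33 ± 0.22), Slco1a1 (-7.07 ± 0.23), C8b (-6.45 ± 0.45) and C8a (-4.86 ± 0.38) fell. Other large rises were Sult2a2 (6.50 ± 0.33), Cbr3 (6.22 ± 0.48), Psat1 (6.18 ± 0.21), Tnfrsf12a (5.56 ± 0.38), the cornified envelope gene Sprr1a (4.97 ± 0.22), the tubulin gene Tubb6 (4.97 ± 0.63, with normal 1 at 71.3 and the other normal livers at 6.8 to 10.3) and Gpx2 (4.84 ± 0.24), and other large falls were Cyp2c54 (-5.73 ± 0.20), Cyp2c50 (-5.51 ± 0.63), Upp2 (-4.79 ± 0.40), Cyp4f14 (-4.43 ± 0.24), Saa1 (-4.25 ± 0.55) and Prodh2 (-4.08 ± 0.44). The signal of Sult2a2, Cyp2c54 and Cyp2c50 is uncertain between near-identical family members. The named genes had adjusted p of at most 0.000673. Of 15307 probe sets, 4353 passed, 2716 higher and 1637 lower (62.4% higher), and 2135 of them changed at least 2-fold (1396 higher, 739 lower). By representative probe sets 2701 genes passed, 1640 higher and 1061 lower. The median of all tested probe sets was 0.11, which was not subtracted from the changes, and the split depended on the scaling. With each array scaled to a common median it was -0.12 and the split was 1651 higher and 2514 lower (39.6% higher). With quantile normalization the median was -0.02 and the split was 2327 and 2170 (51.7% higher). The count was 2477 without Fah p21 off 1, 2563 without Fah p21 off 2, and 1824 with only the genotype-matched mouse on NTBC as control.

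Of the G2/M and mitosis genes 24 of 27 rose and 3 did not pass (24 rose adjusted over the list alone), with median 2.31, camera adjusted p = 1.09e-10, and adjusted p = 0.23 with an estimated correlation; relative to all probe sets the median was 2.21. Beside Cdk1 these were led by the ubiquitin-conjugating enzyme gene Ube2c (4.60 ± 0.63), Birc5 (3.83 ± 0.55) and the proliferation marker Mki67 (3.77 ± 0.60). Without Fah p21 off 2 the G2/M median was 1.19, and the list passed. Of the G1/S and replication genes 19 of 26 rose, 1 fell and 6 did not pass (20 rose and 2 fell adjusted over the list alone), with median 1.20, camera adjusted p = 1.5e-06, and adjusted p = 0.278 with an estimated correlation. Mcm2 rose (3.53 ± 0.23) and Mcm10 fell (-2.62 ± 0.30). Of the DNA repair genes 8 of 21 rose, 0 fell and 13 did not pass (9 rose and 1 fell adjusted over the list alone), with median 0.60, camera adjusted p = 0.018, and adjusted p = 0.401 with an estimated correlation. Brca1 (2.53 ± 0.24) and Rpa2 (1.68 ± 0.26) rose. Without Fah p21 off 2 the DNA repair call ended (median 0.41), and with median scaling its median was 0.37. Of the cell cycle inhibitors 7 of 13 rose, 1 fell and 5 did not pass (7 rose and 1 fell adjusted over the list alone) with median 0.87 and camera adjusted p = 0.0721, and Cdkn2b rose (2.76 ± 0.41). This list passed without normal 2 (median 0.85) or Fah p21 off 1 (1.02), with median scaling (0.64) and over the mean of each gene's probe sets (1.01). Among these genes the highest adjusted p was 0.000902.

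Among p53 targets 18 of 25 rose and 7 did not pass (19 rose adjusted over the list alone), with median 1.60, camera adjusted p = 4.72e-09, and adjusted p = 0.0568 with an estimated correlation. Rises included Gtse1 (3.77 ± 0.33) and Psrc1 (3.26 ± 0.15), both genes of the mitotic spindle, and the BH3-only gene Pmaip1 (3.32 ± 0.54). Cdkn1a is in that list through its _at probe set, which rose (3.57 ± 0.38), while the _a_at probe set was at -1.03 ± 0.39, adjusted p = 0.0734. Of the Nrf2 targets 23 of 26 rose, 1 fell and 2 did not pass (23 rose and 1 fell adjusted over the list alone), with median 1.37, camera adjusted p = 9.68e-11, and adjusted p = 0.126 with an estimated correlation, including Slc7a11 (3.60 ± 0.35) and Srxn1 (3.19 ± 0.15). Of the fetal list 14 of 17 rose and 3 did not pass (14 rose adjusted over the list alone), with median 2.17, camera adjusted p = 3.31e-08, and adjusted p = 0.0568 with an estimated correlation, including Cd24a (3.47 ± 0.33) and Scd2 (3.26 ± 0.38). Of the cholangiocyte markers 6 of 8 rose and 2 did not pass (6 rose adjusted over the list alone), with median 2.13, camera adjusted p = 0.000676, and adjusted p = 0.109 with an estimated correlation and a median of 1.22 with no filter. Prom1 (3.46 ± 0.37) and Bicc1 (2.82 ± 0.24) rose. Of the macrophage markers 12 of 19 rose and 7 did not pass (13 rose adjusted over the list alone), with median 0.67, camera adjusted p = 0.000195, and adjusted p = 0.401 with an estimated correlation, Gpnmb (3.47 ± 0.55) and Lyz2 (1.63 ± 0.22) among them. Of the stellate cell and matrix markers 10 of 19 rose and 9 did not pass (12 rose adjusted over the list alone), with median 0.62, camera adjusted p = 0.000195, and adjusted p = 0.269 with an estimated correlation, including Col3a1 (2.55 ± 0.55) and Lum (1.45 ± 0.19). With median scaling the macrophage and stellate medians were 0.44 and 0.40. Of the heat shock genes 3 of 13 rose and 10 did not pass (3 rose adjusted over the list alone) with median 0.30 and camera adjusted p = 0.222, and Hspb1 rose (2.91 ± 0.26). The heat shock list passed with quantile normalization (median 0.43) and without normal 1 (0.54). The named genes had adjusted p of at most 0.00526.

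Of the complement and coagulation genes 23 of 25 fell and 2 did not pass (23 fell adjusted over the list alone), with median -1.70, camera adjusted p = 3.15e-18, and adjusted p = 0.0568 with an estimated correlation. F7 (-2.30 ± 0.21) and C9 (-2.25 ± 0.37) fell. In gluconeogenesis and amino acid catabolism 1 of 18 rose, 15 fell and 2 did not pass (1 rose and 16 fell adjusted over the list alone), with median -1.32, camera adjusted p = 4.5e-11, and adjusted p = 0.0568 with an estimated correlation, Hal lowest (-3.06 ± 0.19). Every tested urea cycle gene fell, 9 of 9 (9 adjusted over the list alone), with median -0.93, camera adjusted p = 1.85e-07, and adjusted p = 0.0938 with an estimated correlation. In phenylalanine and tyrosine catabolism 8 of 10 fell and 2 did not pass (9 fell adjusted over the list alone), with median -1.24, camera adjusted p = 2.87e-07, and adjusted p = 0.109 with an estimated correlation, Tat at -2.40 ± 0.23. Of the bile acid genes 1 of 17 rose, 13 fell and 3 did not pass (1 rose and 14 fell adjusted over the list alone), with median -1.59, camera adjusted p = 8.97e-10, and adjusted p = 0.0568 with an estimated correlation. Of the hepatocyte identity genes 15 of 18 fell and 3 did not pass (15 fell adjusted over the list alone), with median -0.71, camera adjusted p = 5.54e-11, and adjusted p = 0.0568 with an estimated correlation and a median of -0.23 after quantile normalization. Of the male-biased genes 7 of 9 fell and 2 did not pass (7 fell adjusted over the list alone), with median -2.64, camera adjusted p = 5.58e-08, and adjusted p = 0.0568 with an estimated correlation and a median of -1.74 over the mean of each gene's probe sets. In fatty acid synthesis 10 of 16 fell and 6 did not pass (10 fell adjusted over the list alone), with median -0.89, camera adjusted p = 0.000787, and adjusted p = 0.172 with an estimated correlation, Fads1 at -2.12 ± 0.26. In cholesterol synthesis 6 of 19 fell and 13 did not pass (6 fell adjusted over the list alone), with median -1.0, camera adjusted p = 0.000195, and adjusted p = 0.403 with an estimated correlation, but without Fah p21 off 2 the call ended (median -0.10). Of the acute phase genes 4 of 27 rose, 16 fell and 7 did not pass (4 rose and 16 fell adjusted over the list alone), with median -0.85, camera adjusted p = 2.04e-05, and adjusted p = 0.253 with an estimated correlation and a median of -0.32 after quantile normalization, and the lipocalin gene Lcn2 rose (4.05 ± 0.49). Of the xenobiotic genes 1 of 22 rose, 10 fell and 11 did not pass (1 rose and 11 fell adjusted over the list alone), with median -0.69, camera adjusted p = 6.94e-06, and adjusted p = 0.0568 with an estimated correlation. After quantile normalization the xenobiotic call ended (median -0.34). Among these genes the highest adjusted p was 0.00116.

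The third comparison, Fah p21 off (n = 2) against Fah off (n = 3), tested the difference itself. The mitotic kinase gene Cdk1 rose 14-fold (3.81 ± 0.47, adjusted p = 0.0451), from signals of 30 to 85 to 549 and 1617, and the ribonucleotide reductase gene Rrm2 (3.50 ± 0.49, adjusted p = 0.0472) and the helicase gene Mcm5 (2.36 ± 0.32, adjusted p = 0.0472) rose with it. The change of Rrm2 was 2.34 without Fah p21 off 2 and 4.68 without Fah p21 off 1. Igfbp2, an insulin-like growth factor binding protein gene, fell (-1.72 ± 0.24, adjusted p = 0.0472). The Cdkn1a _a_at probe set fell (-6.13 ± 0.41, adjusted p = 0.000201) while its _at probe set was at -0.82 ± 0.40, adjusted p = 0.644. With 1 probe set that has no gene symbol here, which rose (3.84 ± 0.54, adjusted p = 0.0472), these were the 6 of 15307 probe sets that passed, 4 higher and 2 lower; 1234 had an unadjusted p under 0.05. The median of all probe sets was 0.06, and -0.10 with median scaling. With quantile normalization 4 passed, 2 higher and 2 lower, and with median scaling 3 passed, 2 higher and 1 lower. The Cdkn1a _a_at probe set passed in 21 of 22 alternatives (adjusted p from 4.59e-05 to 0.152). Its call ended when each knockout was set against its own mouse on NTBC (-4.81 ± 0.56), where 1 probe set passed and 0 of the 6 did. With those single mice as controls the other changes kept their sign, at 3.80 ± 0.97 for Cdk1, 3.15 ± 1.04 for Rrm2, 2.61 ± 0.56 for Mcm5 and -1.77 ± 0.50 for Igfbp2, and all standard errors were larger. Over the alternatives the adjusted p ran from 0.0184 to 0.686 for Cdk1, from 5.98e-05 to 0.959 for Rrm2, from 0.0122 to 0.582 for Mcm5 and from 0.0336 to 0.895 for Igfbp2, and they passed in 6 of 20, 3 of 22, 5 of 22 and 2 of 22. The changes themselves ran from 3.31 to 4.04 for Cdk1, from 2.34 to 4.68 for Rrm2, from 1.93 to 2.81 for Mcm5 and from -2.03 to -1.42 for Igfbp2. The values for Cdk1 leave out the settings without Fah p21 off 1 or without Fah p21 off 2, where it fell below the filter. Its range is therefore not comparable with that of Rrm2. The count was 1 without any single normal array (normal 1, normal 2, normal 3 or normal 4) or any single Fah off array (Fah off 1, Fah off 2 or Fah off 3), 2 without Fah p21 off 2, and 58 without Fah p21 off 1 (51 higher, 7 lower).

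By list, 1 of 27 G2/M and mitosis genes rose over all probe sets and 25 rose adjusted over the list alone, with median 1.92, camera adjusted p = 8.86e-32, and adjusted p = 0.411 with an estimated correlation. Its median was 1.85 above that of all probe sets, its adjusted p over 17 alternatives ran from 4.44e-42 to 0.411, and the survivin gene Birc5 was at 3.79 ± 0.58, adjusted p = 0.0623. In G1/S and DNA replication 2 of 26 rose over all probe sets, and 21 rose and 1 fell adjusted over the list alone, with median 0.95, camera adjusted p = 1.57e-18, and adjusted p = 0.411 with an estimated correlation. The G2/M median was 1.16 without Fah p21 off 2, and the G1/S median was 0.56 without Fah p21 off 2 and 1.51 without Fah p21 off 1. Here too the filter could keep a gene through the Fah p21 off livers alone, which may raise the shares and medians of both lists. With fry, which tests whether a list's genes move one way on balance, adjusted p was 0.0769 for G2/M and 0.0776 for G1/S. Per liver, the mean G2/M level over the wildtype livers was 0.54, 0.55 and 0.17 in the Fah off livers and 1.69 and 3.07 in the Fah p21 off livers. Of the p53 targets, 0 of 25 passed with limma and 3 had an unadjusted p under 0.05 (median 0.06, camera adjusted p = 0.925, and adjusted p = 0.961 with an estimated correlation), and the median was -0.10 with median scaling. Ckap2, a spindle gene in that list, was at 1.80 ± 0.30, adjusted p = 0.076.

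Marker lists of other cells had medians above 0 beside the cell cycle lists. Of the stellate cell and matrix markers, 0 of 19 passed with limma and 7 had an unadjusted p under 0.05 (median 0.52, camera adjusted p = 1.99e-05, and adjusted p = 0.496 with an estimated correlation); 4 rose adjusted over the list alone, and Pdgfrb was at 0.97 ± 0.29, adjusted p = 0.363. Of the macrophage markers, 0 of 19 passed with limma and 2 had an unadjusted p under 0.05 (median 0.36, camera adjusted p = 0.00214, and adjusted p = 0.699 with an estimated correlation). In DNA repair, 0 of 21 passed with limma and 7 had an unadjusted p under 0.05 (median 0.48, camera adjusted p = 0.000175, and adjusted p = 0.496 with an estimated correlation), with H2ax at 1.33 ± 0.28, adjusted p = 0.159. In cholesterol synthesis, 0 of 19 passed with limma and 3 had an unadjusted p under 0.05 (median 0.51, camera adjusted p = 0.00993, and adjusted p = 0.806 with an estimated correlation). The lists below 0 were heat shock, where 0 of 13 passed with limma and 3 had an unadjusted p under 0.05 (median -0.38, camera adjusted p = 7.04e-05, and adjusted p = 0.496 with an estimated correlation), fatty acid oxidation, where 0 of 19 passed with limma and 1 had an unadjusted p under 0.05 (median -0.24, camera adjusted p = 0.000175, and adjusted p = 0.496 with an estimated correlation), Nrf2 targets, where 0 of 26 passed with limma and 0 had an unadjusted p under 0.05 (median -0.19, camera adjusted p = 0.000598, and adjusted p = 0.673 with an estimated correlation), and hepatocyte identity, where 0 of 18 passed with limma and 1 had an unadjusted p under 0.05 (median -0.09, camera adjusted p = 0.0147, and adjusted p = 0.634 with an estimated correlation). Hspb1 was at -0.68 ± 0.27, adjusted p = 0.55, Pdk4 at -0.62 ± 0.23, adjusted p = 0.485 and Fth1 at -0.25 ± 0.12, adjusted p = 0.633. The hepatocyte identity median was 0.06 after quantile normalization and -0.25 with median scaling. Quantile normalization ended the calls for fatty acid oxidation (-0.12) and Nrf2 targets (-0.07), and median scaling moved macrophages to 0.20, DNA repair to 0.32, fatty acid oxidation to -0.40 and Nrf2 targets to -0.35. Over the mean of each gene's probe sets fatty acid oxidation was at -0.12 and heat shock at -0.20. Single arrays decided several of these. Without Fah off 1 the hepatocyte identity call ended (-0.06). Without Fah off 3 those of cholesterol synthesis (0.22) and macrophages (0.24) ended, and without Fah p21 off 1 that of cholesterol synthesis (-0.01). Without Fah p21 off 2 those of DNA repair (0.24), Nrf2 targets (-0.00619) and hepatocyte identity (-0.08) ended. In that setting heat shock was at -0.23, fatty acid oxidation at -0.16 and cholesterol synthesis at 0.88, and without Fah p21 off 1 the Nrf2 targets were at -0.30.

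The other 22 lists tested with camera had adjusted p of 0.111 or more in this comparison. Among them were complement and coagulation (median 0.23), the urea cycle (0.12, where Cps1 was at 0.71 ± 0.15, adjusted p = 0.136), the fetal list (0.08) and cholangiocyte markers (0.09). The fetal list was at -0.08 and the cholangiocyte markers at -0.07 with median scaling, the urea cycle list at -0.04, and the fetal list at -0.09 after quantile normalization. Acute phase, complement, fatty acid synthesis, gluconeogenesis and urea cycle lists passed after quantile normalization, with medians of 0.25, 0.16, 0.30, 0.21 and 0.10. Left-out arrays also brought lists past the threshold. These were acute phase without Fah off 1 (0.31) or Fah p21 off 1 (0.30), complement without Fah off 1 (0.36), and the unfolded protein response (-0.20) and fatty acid synthesis (0.41) without Fah off 2. Xenobiotic genes passed without Fah off 2 (-0.10) or Fah off 3 (-0.11), and bile acid genes without Fah off 3 (-0.28) or Fah p21 off 2 (-0.14).

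Log2 changes in the Fah off and Fah p21 off livers were then compared across probe sets, which are not independent replicates. Afp, Ly6d, Cbr3 and Psat1 rose and Hsd3b5, Slco1a1, C8a and C8b fell in both. Pearson's r was 0.905 (Spearman's rho 0.869) over 15307 probe sets, and 83.4% had the same sign. Both comparisons use the same normal livers, and 100 simulations of unchanged groups against them gave a mean r of 0.377 and 62.3% of the same sign. The covariance was 0.659 against a simulated 0.024. With the normal livers split 2 and 2 so that none was shared, r was 0.755 to 0.868. Both comparisons called 2208 probe sets higher, where independent lists would share 547, and 1440 lower, where independent lists would share 252, values that leave out the shared normal livers; 1 was called in opposite directions.

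On the 430 2.0 array, 2 other double knockout livers off NTBC were set against 1 normal liver, whose spread had to be assumed equal to theirs, and every call there rests on that. Cell cycle genes were higher there too, by 3.99 ± 0.40 for Mki67, 3.53 ± 0.26 for Cdk1, 3.48 ± 0.29 for Birc5 and 3.82 ± 0.29 for Rrm2. Mcm5 was at 2.38 ± 0.30 and Igfbp2 at -1.85 ± 0.23. Afp (6.57 ± 0.22), Ly6d (6.97 ± 0.26), Cbr3 (6.29 ± 0.23) and Psrc1 (5.57 ± 0.31) were also higher and C8b (-6.14 ± 0.30) lower; the highest adjusted p of these genes was 0.00391. All 37 tested G2/M genes were higher in both livers and 36 of them passed, with a median of 3.60 (3.69 and 3.54 per liver). In G1/S and DNA replication 21 of 33 passed higher and 1 lower (median 1.60), in p53 targets 19 of 27 higher (1.98), in Nrf2 targets 17 of 27 higher (1.34), and in the fetal list 14 of 18 higher (2.92). Of the complement and coagulation genes 20 of 25 passed lower (-1.72), and of the male-biased genes 5 of 8 (-1.92). Stellate cell and matrix markers had 8 of 19 higher (0.97) and macrophage markers 3 of 19 (0.31). In all, 3101 of 26925 probe sets passed, 2077 higher and 1024 lower. The count was 1002 with no filter and 1225 without the intensity trend. The median of all probe sets was 0.07, and it was -0.06 with median scaling.

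Across the array designs, the log2 changes of the double knockout on 430A, with normal 4 left out so that no mouse was shared, had r = 0.823 (rho = 0.778) with those on 430 2.0 over 14469 probe sets. Of 4401 probe sets called on 430A, 97.2% had the same sign on 430 2.0, and of all 14469 it was 79.2%. With no filter r was 0.683. Normal 4, taken from its replicate number to be the same mouse on both designs, had r = 0.858 between the signals of the designs.

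**Figure D3:**
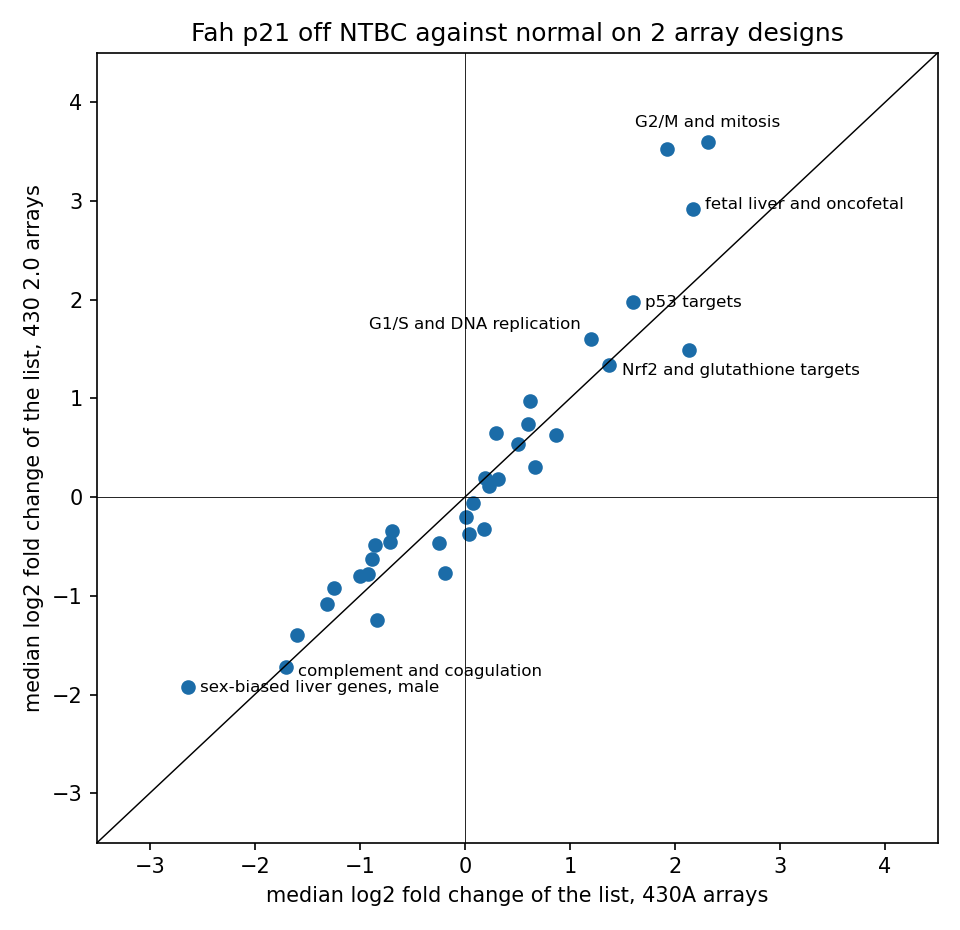
Median log2 fold change of each gene list between Fah p21 off and normal livers on the 430A arrays (horizontal axis) and on the 430 2.0 arrays (vertical axis), 1 point per list, with the line of equal change. G2/M and mitosis is at 2.31 and 3.60, and complement and coagulation at -1.70 and -1.72.

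The normal group held 2 wildtype livers, 1 of them on NTBC, and 1 liver of each knockout on NTBC, and no contrast between these was run here. The wildtype pair differed at least 2-fold in 334 of 15307 probe sets, and the other normal pairs in 609 to 1107. Macrophage markers averaged 0.90 above the wildtype livers in normal 4 and 0.38 in normal 3, against 1.05, 0.98 and 0.48 in the Fah off livers and 1.17 and 1.33 in the Fah p21 off livers. The G2/M list was at 0.30 in normal 4 and 0.12 in normal 3. Heat shock genes averaged 0.51 above the wildtype mean in normal 1, and -0.44 to -0.51 in the other normal livers. Cholesterol synthesis genes were at 0.41 in normal 1 and -0.41, -0.41 and -0.73 in normal 2, 3 and 4, against -1.40, -1.40 and -2.26 in the Fah off livers and -0.60 and -1.76 in the Fah p21 off livers. Fah off 1 and 2 differed at least 2-fold in 225 probe sets, and Fah off 3 differed from them in 870 and 805. The Fah p21 off livers differed in 552.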

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

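Tests of cell makeup, array batch, mouse sex, hepatocyte share and the Cdkn1a transcripts were chosen only after the results were seen. The tests of other splits of the arrays and of growth hormone genes were written before theirs. The test of scaling was also written before its own result, but its bound was set from the G2/M difference already seen.

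In 11 of 208 named probe sets 1 of the 4 normal livers stood apart from the other 3, by a gap above Dixon's 95% critical share of the group's range, where chance gives about 1 in 20. Normal 4 was the liver apart for Cd68 (gap 0.932 of the range), Chek1 (0.832), Kap (0.863), Scd1 (0.951) and Tspan8 (0.830). Normal 3 was apart for Fabp4 (0.855), Mcm6 (0.939) and Upp2 (0.853), normal 1 for Klf1 (0.82935) and Tubb6 (0.880), and normal 2 for Cyp2c54 (0.911). Of 34 list levels, 1 had such a gap, heat shock proteins in normal 1 (0.929).

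The test of the difference between knockouts off NTBC passed for Cdk1 (3.81), the probe set without a symbol (3.84), Rrm2 (3.50), Mcm5 (2.36), Igfbp2 (-1.72) and the Cdkn1a _a_at probe set (-6.13), log2 Fah p21 off minus Fah off. None of them passed when each knockout was set against its own single mouse on NTBC, where the changes were 3.80, 3.76, 3.15, 2.61, -1.77 and -4.81 in that order, with standard errors of 0.50 to 1.11 in place of 0.24 to 0.54. Lists past camera's threshold at the preset correlation were G2/M and mitosis (median 1.92), G1/S and DNA replication (0.95), stellate cells and matrix (0.52), cholesterol synthesis (0.51), DNA repair (0.48), macrophages (0.36), heat shock proteins (-0.38), fatty acid oxidation (-0.24), Nrf2 targets (-0.19) and hepatocyte identity (-0.094, but 0.061 after quantile normalization). None passed with an estimated correlation, where adjusted p was 0.411 or more. Calls ended without Fah off 1 for hepatocyte identity (-0.062), without Fah off 3 for cholesterol synthesis (0.22) and macrophages (0.24), without Fah p21 off 1 for cholesterol synthesis (-0.00641), and without Fah p21 off 2 for DNA repair (0.24), Nrf2 targets (-0.00619) and hepatocyte identity (-0.083).

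The first pattern weighed is the higher level of cell cycle genes in Fah p21 off than in Fah off livers. Scaling between arrays is argued against, since the G2/M median was 1.82 after quantile normalization. More macrophages or stellate cells of unchanged cycling are argued against as the whole cause, since the higher of those marker medians was 0.52, far below 1.92. On the other design the list was also raised in other double knockout livers off NTBC, with a median of 3.60 over 1 normal liver. That bears on the rise over normal only. The design held no Fah off liver, so a batch that separates the knockouts on 430A stays open. Relative to the wildtype mean on 430A, the list was at 0.54, 0.55 and 0.17 in the Fah off livers, 0.12 and 0.30 in normal 3 and 4, and 1.69 and 3.07 in the Fah p21 off livers. Array batches are not given in the sources used here. Loss of p21, which the design names, may account for the pattern and stays open as a hypothesis.

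The second pattern is the fall of male-biased liver genes off NTBC, with a median of -2.56 in Fah off livers. Mice of the other sex are argued against, since the lowest signal of the Y-linked gene Eif2s3y off NTBC was 237.1. A smaller share of hepatocytes is argued against as the whole cause, since the hepatocyte identity median was -0.53. Weaker growth hormone signalling, which maintains male-biased expression, stays a candidate explanation: 57.1% of 7 tested genes fell, namely Igf1 (-1.07), Igfals (-3.05), Ghr (-2.40) and Onecut1 (-1.62). It met its bound by 1 gene, and the STAT5 targets Socs2 (-0.27) and Cish (-0.52) did not pass. Bcl6 (-0.03) did not pass either. The test counted only falls, and whether Bcl6 should fall was not checked, so its value speaks neither way. Liver genes fell broadly off NTBC, with 14 of 18 hepatocyte identity genes lower, so the falls of these genes do not single out this explanation.

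The last pattern is the disagreement of the Cdkn1a probe sets in double knockout livers off NTBC. The _at probe set was higher than in normal 4 in 4 of 4 such livers, while the _a_at probe set stayed at or below the 14.4th percentile of its array, and the mean signal of the _at probe set was 55.9% of that in Fah off livers. These values describe the pattern and decide between no explanations. A transcript of the altered locus that only the _at probe set measures and another transcript measured by it cannot be told apart, since no probe sequences were used here.

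For the count in Fah off against normal, the 7 arrays were split into 4 and 3 in all 35 ways. The real split gave 5437 probe sets and the highest other split 11. That the real split gave the most argues against an arbitrary grouping, but 35 splits are too few to exclude chance. The size of the gap adds nothing, since mixed splits put any large difference into the spread. A batch or genotype mix that follows the groups would give the same result.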

How the results depend on the processing

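Wildtype mice as the only controls, median scaling of gene lists, and the named genes between the knockouts under other controls or with 2 groups in the fit were alternatives chosen only after results were seen. The counts against normal moved by over 1.5 times with the genotype-matched mouse as control (2572 in Fah off, 1824 in Fah p21 off), with a 2-fold minimum (2265 and 2135) and with representative probe sets only (3381 and 2784), the last 2 settings from a further threshold and from fewer probe sets tested. The matched mouse changes both the number and the kind of controls, and the cause of that fall was not tested. Other settings kept them within 1.5 times, except that leaving out 1 array gave 2477 to 4636 in Fah p21 off. Between Fah p21 off and Fah off, where 6 passed, the count was 1 with the 60th percentile filter, with no offset, with knockout mice on NTBC, the genotype-matched mouse (none of the 6, at changes of 3.80 for Cdk1, 3.15 for Rrm2, 2.61 for Mcm5, -1.77 for Igfbp2 and -4.81 for Cdkn1a) or wildtype mice as controls, 2 with robust limma and with only 2 groups in the fit, 3 with median scaling, 13 without the trend, 14 with the larger offset, and 1 to 58 over the arrays left out. On 430 2.0 the count was 1002 with no filter and 1225 without the trend. The correlation between array designs was 0.683 with no filter, and that between the knockouts 0.755 at the lowest with the normal arrays split. The cause of the other moves was not tested.

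With an estimated correlation the calls ended, at the same medians, for Nrf2 targets (1.44) and p53 targets (1.15) in Fah off, for G1/S (1.20) and G2/M (2.31) in Fah p21 off against normal, and for G1/S (0.95) and G2/M (1.92) between the knockouts, and with fry for the last pair (0.95 and 1.92). Fry also ended the other 8 list calls between the knockouts, that of macrophages in Fah off (0.40) and that of cholesterol synthesis in Fah p21 off against normal (-1.0), and it called 6 further lists in Fah off and 5 in Fah p21 off against normal. Same-numbered arrays gave no sign of pairing. Their deviations from the group means had correlations of -0.22, -0.17 and -0.28 between normal and Fah off. These were -0.080 and 0.061 between normal and Fah p21 off, and 0.044 and 0.071 between the knockouts. None of the first 3 normal arrays correlated best with the Fah off array of its number. Deviations from the mean of so few arrays constrain each other, so these correlations cannot exclude pairing. With the replicate number as a block the counts were 4463, 3479 and 1, and of the list calls that for cholesterol synthesis between the knockouts ended (0.32) and that for bile acids began (-0.13).

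Of 6074 values of named genes under an alternative, 5763 stayed on their side of the threshold, 249 no longer passed, 26 newly passed and 36 changed sign. Of 1524 list medians these were 1357, 66, 42 and 59. Of lists that had passed, hepatocyte identity (with quantile normalization) and cholesterol synthesis (without Fah p21 off 1) between the knockouts were those that changed sign, and of genes that had passed, Tef, Sox4, Hspa4, Fabp4, Ighm and Cdkn1a, each by its other probe sets. The cause was not tested. The sign changed with no filter in Fah off against normal adipose (-0.059), erythroid (0.15), and in Fah p21 off against normal adipose (-0.073), erythroid (0.14), and in Fah p21 off against Fah off fetal liver list (-0.042). With quantile normalization it changed in Fah p21 off against normal endothelial (-0.16), lymphocytes (-0.069), Xist (-0.066), and in Fah p21 off against Fah off circadian clock (-0.000502), fetal liver list (-0.095), glycolysis (-0.021), hepatocyte identity (0.061), neutrophils (-0.00805), tyrosine catabolism (0.055), male-biased genes (-0.00896), xenobiotic (0.065), Fah (-0.14). With median scaling it changed in Fah p21 off against normal ATF4 (-0.034), fatty acid oxidation (-0.15), endothelial (-0.21), lymphocytes (-0.043), Xist (-0.068), and in Fah p21 off against Fah off circadian clock (-0.018), fetal liver list (-0.080), gluconeogenesis (-0.069), glycolysis (-0.14), cholangiocytes (-0.072), endothelial (-0.11), neutrophils (-0.011), p53 targets (-0.099), male-biased genes (-0.15), urea cycle (-0.044), Fah (-0.13). With the replicate block it changed in Fah p21 off against normal fatty acid oxidation (-0.017), neutrophils (0.030), and in Fah p21 off against Fah off glycolysis (-0.029), male-biased genes (-0.17), Alas2 (-0.099), Fah (-0.83). Over the mean of a gene's probe sets it changed in Fah off against normal fatty acid oxidation (-0.025), and in Fah p21 off against normal fatty acid oxidation (-0.012), and in Fah p21 off against Fah off glycolysis (-0.018). A gene's other probe sets had the opposite sign in Fah off against normal Sox4 (-0.22), Hspa4 (-0.42, -0.35), Fabp4 (-0.077), Ighm (-0.46, -0.91, -1.02, -0.28), and in Fah p21 off against normal Tef (0.47), Hspa4 (-0.18, -0.097), Fabp4 (-0.035), Ighm (-0.30, -0.78, -0.91), and in Fah p21 off against Fah off Cpt2 (0.16), Dpys (0.79), Hspb8 (0.022), Nr5a2 (0.22), Kdm5d (-0.024). Those of Cdkn1a were at -1.03 and 3.57 in Fah p21 off against normal.

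Over the arrays left out the sign changed in Fah off against normal for endothelial -0.19 to 0.026. In Fah p21 off against normal the ranges were endothelial -0.085 to 0.19, Xist -0.071 to 0.39, fatty acid oxidation -0.077 to 0.15, neutrophils -0.33 to 0.038, lymphocytes -0.11 to 0.49. Between the knockouts they were fetal liver list -0.056 to 0.19, xenobiotic -0.11 to 0.044, apoptosis regulators -0.050 to 0.045, Fah -0.023 to 0.084, circadian clock -0.10 to 0.35, endothelial -0.11 to 0.20, erythroid -0.076 to 0.57, tyrosine catabolism -0.069 to 0.035, male-biased genes -0.30 to 0.36, Alas2 -0.44 to 1.01, cholesterol synthesis -0.00641 to 0.88, ATF4 -0.20 to 0.011, cholangiocytes -0.065 to 0.27, Atf4 -0.71 to 0.10, Prom1 -0.094 to 1.30. Signal over background limits dim genes: 15307 of 22690 probe sets passed the filter, and fold changes near the offset are understated.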

Other observations

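Of the tests in this part, the median scaling of gene lists was chosen only after results were seen. In Fah off livers (n = 3) against normal (n = 4), stress and fuel genes changed inside lists that camera did not call. In the list of ATF4, ER stress and the unfolded protein response 8 of 23 rose, 4 fell and 11 did not pass (8 rose and 5 fell adjusted over the list alone), with median 0.35 and camera adjusted p = 0.168. Psat1, the hormone gene Fgf21 (4.44 ± 0.50), Atf3 (2.90 ± 0.34) and Asns (2.83 ± 0.41) were among those that rose. Of the fatty acid oxidation genes 7 of 19 rose, 3 fell and 9 did not pass (7 rose and 3 fell adjusted over the list alone), with median 0.14 and camera adjusted p = 0.365. Pdk4, a brake on pyruvate oxidation, Acot1 (3.50 ± 0.35) and Ehhadh (1.59 ± 0.17) rose. In glycolysis 5 of 12 rose, 2 fell and 5 did not pass (6 rose and 2 fell adjusted over the list alone), with median 0.43 and camera adjusted p = 0.107. Pkm, the pyruvate kinase gene of non-liver tissues, rose (3.29 ± 0.29) and its liver counterpart Pklr fell (-1.90 ± 0.20), and in Fah p21 off livers they were at 3.02 ± 0.33 and -1.78 ± 0.23. Both the fatty acid oxidation and the glycolysis list passed after quantile normalization, with medians of 0.18 and 0.37, and over the mean of each gene's probe sets the fatty acid oxidation median was -0.025. Of the apoptosis regulators 4 of 20 rose, 2 fell and 14 did not pass (4 rose and 1 fell adjusted over the list alone), with median 0.15 and camera adjusted p = 0.334, and Bid (1.60 ± 0.17) and Casp8 (0.95 ± 0.14) rose. In DNA repair 5 of 21 rose, 2 fell and 14 did not pass (5 rose and 2 fell adjusted over the list alone), with median 0.15 and camera adjusted p = 0.414, and Brca1 rose (2.35 ± 0.21) and Parp1 fell (-0.90 ± 0.13). Of the clock genes 1 of 11 rose, 4 fell and 6 did not pass (1 rose and 5 fell adjusted over the list alone), with median -0.40 and camera adjusted p = 0.0906, with Dbp at -2.15 ± 0.39 and Nr1d1 at -1.07 ± 0.25. The named genes of these lists had adjusted p of at most 0.00701.

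Of the erythroid markers 1 of 5 rose, 2 fell and 2 did not pass (1 rose and 2 fell adjusted over the list alone), with median -0.93 and camera adjusted p = 0.365, with the erythroid heme synthesis gene Alas2 lower (-4.05 ± 0.58) and the transferrin receptor gene Tfrc higher (1.70 ± 0.38). Of the endothelial markers 1 of 13 rose, 1 fell and 11 did not pass (1 rose and 1 fell adjusted over the list alone), with median -0.04 and camera adjusted p = 0.605, with the lymphatic and sinusoidal marker Lyve1 higher (1.75 ± 0.28). The endothelial mean was 0.0026 and the camera direction was down. Of the lymphocyte markers 1 of 9 rose, 1 fell and 7 did not pass (0 rose and 0 fell adjusted over the list alone), with median -0.28 and camera adjusted p = 0.59. Ighm rose by its representative probe set (0.71 ± 0.21), while its other 4 probe sets were at -0.28 to -1.02. Of the neutrophil markers 0 of 8 passed with limma and 1 had an unadjusted p under 0.05, with median -0.26 and camera adjusted p = 0.318. Of the adipose, pancreas and kidney markers 1 of 6 rose and 5 did not pass (1 rose adjusted over the list alone), with median 0.21 and camera adjusted p = 0.408. That gene was Fabp4 (4.59 ± 0.21), whose other probe set was at -0.077. The 3 female-biased genes tested had a median of 1.49 and 1 rose, Sult2a2; of the 4 sex-linked transcripts 0 passed with limma and 1 had an unadjusted p under 0.05 (median -0.19). The named genes of these lists had adjusted p of at most 0.0208.

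In Fah p21 off livers (n = 2) against normal, Fgf21 (3.77 ± 0.57), Atf3 (2.67 ± 0.39), Acot1 (3.15 ± 0.40) and Lyve1 (2.04 ± 0.31) rose too and Alas2 fell (-3.58 ± 0.66), with adjusted p of at most 0.00219. Median, mean and test differed in sign for some lists. Fatty acid oxidation there had a median of 0.078, a mean of 0.46 and a camera direction of down, and its median was -0.15 with median scaling. Endothelial markers had a median of 0.015 (-0.21 with median scaling) and a mean of 0.09 with camera down. Between Fah p21 off and Fah off livers, glycolysis (median 0.016, mean 0.06) and male-biased genes (median 0.013, mean 0.23) had a camera direction of down, and phenylalanine and tyrosine catabolism had a median of -0.034 and a mean of 0.01. All of these last medians had the other sign after quantile normalization (-0.021, -0.00896 and 0.055). The sex-linked transcripts in Fah p21 off against normal had a median of 0.04 and a mean of -0.04.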
